A study of Homo sapiens with 4 samples.

How the data were processed

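ATAC-seq, which reads out accessible DNA by the sites where a transposase can insert sequencing adapters, was run on K562 cells, an established human chronic myelogenous leukaemia line. Per the labels, cells were left untreated or were exposed for 4 h to doxorubicin (Doxo, 10 µM), N,N-dimethyldoxorubicin (diMe-Doxo, 10 µM) or aclarubicin (Acla, 20 µM), with 1 GEO sample per group, and libraries were sequenced on a HiSeq4000. The authors deposited, for each drug, a list of regions with more reads in the treated than in the control libraries. Each list holds values for 2 treated and 2 control libraries. The labels do not say whether the 2 libraries of a group came from separate cultures. No p-value can therefore be taken to measure the spread between cultures, and the spread between these libraries may be technical.

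Reads were placed on GRCh37 and regions were compared with DiffBind, per the submitters' processing notes. The aligner, the peak caller, the normalization, the test inside DiffBind and all their versions are not given in the sources used here. The column meanings were worked out from the values, since the lists have no header. In the authors' lists the mean normalized read counts and the fold of treated over control are on a log2 scale, and the fold equals the difference of the group means within 0.01. The deposited p-value of each region and its false discovery rate (FDR) are the authors' own. The deposited signal of each library is a read count per region times 1 factor per library. The lists also give the number of libraries in which the authors called a peak. In all 3 lists the highest p was 0.05 and the lowest log2 fold was 1.5, so they hold gained regions only, and regions that lost signal or did not pass these limits were not analysed here. Coordinates are given as in the lists, which do not say whether the start counts from 0 or from 1.

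Reads were recovered by dividing each library's signal by its smallest step, and 100% of values came out whole within 0.1 reads. The lowest control value is 1 read, and a region with no read may stand at this value, so folds over such controls depend on it. Control reads were identical in both libraries at each of the 33140 regions listed for Doxo and diMe-Doxo, the 32787 listed for Doxo and Acla and the 43402 listed for diMe-Doxo and Acla. The 3 lists therefore share their 2 control libraries. Reads inside listed regions ranged from 3534855 to 7266289 per treated library within its own list and from 120492 to 253175 per control library. These sums cover the listed regions only, and the full depth of the libraries is unknown. Counting intervals for ratios cover counting error only.

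Lists were compared by regions that share at least 1 bp. Regions of different lists either had the same coordinates or did not overlap, with 0 partial overlaps among 100205 regions. Overlap was set beside 100 circular shifts of a list within each chromosome. Errors of shares, Jaccard indices and differences are delete-one-chromosome jackknife standard errors. Intervals of ratios of region counts, per chromosome or over the genome, come from 1000 draws of 1 Mb windows. These errors describe the spread along the genome, not between cultures. Because the comparisons share controls, unchanged drug libraries were simulated against these controls. The overlap of independent lists was computed from a lower bound on the number of regions tested, at least 210400, which follows from the deposited p-values and FDRs if the FDR is a Benjamini-Hochberg adjustment and all 3 lists came from 1 set of regions, and which makes that overlap an upper limit.

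The design assumed 1 library per group and so no test between libraries. Because the lists hold 2, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (limit 0.05) was added after the data had been seen, on recovered reads. Drugs were compared at regions present in both lists, with the authors' library factors put on the scale of the shared controls, or with TMM factors over the shared regions. In simulated data, 100 regions were changed 4-fold and 100 were changed 2-fold. The test found 93% and 28% of these for Doxo against diMe-Doxo (among 33140 regions). It found 89% and 18% for Doxo against Acla (among 32787), and 92% and 22% for diMe-Doxo against Acla (among 43402). False calls made up 6.2%, 0.9% and 5% of the calls. The simulation gave all regions of a comparison the same dispersion and used the authors' factors only, so these rates need not hold for the real calls. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.

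The lists, overlaps, Doxo to diMe-Doxo comparison, chromosome counts and main alternatives were chosen before the data were examined. So was the rule for named regions, which takes for each drug the 3 regions with the lowest FDR, the 3 widest regions and the 3 windows of 1 Mb with the most gained regions. Other named regions and windows were chosen after their values were seen and are given as such. The rule also named genes by their promoters. Gene positions, promoter gene lists, cell type markers and gene names are not reported, because no annotation of GRCh37 was used here. Alternatives covered stricter limits, merged neighbouring regions, lists of equal length, other overlap and shift rules, leaving out each chromosome or library, and other scalings.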

Results

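Accessible chromatin was measured by ATAC-seq in K562 cells after 4 h with 1 of 3 anthracyclines and in untreated cells. Doxorubicin intercalates into DNA and is known both to cause DNA double-strand breaks and to evict histones. N,N-dimethyldoxorubicin carries 2 methyl groups on the amine of the sugar, and aclarubicin is an anthracycline with a longer sugar chain. Both are known to evict histones with few or no breaks. Doxo and diMe-Doxo were given at 10 µM and Acla at 20 µM. The series asks how the chromatin effects of doxorubicin can be set apart from its DNA damage. The data were lists of regions that gained signal over the control, each with 2 treated libraries and the same 2 control libraries.

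With each drug most gained regions lay where no control peak had been called. Doxo had 66720 gained regions covering 60.9 Mb, diMe-Doxo 52784 covering 51.9 Mb and Acla 61295 covering 57.9 Mb. Median widths were 803, 894 and 854 bp. In the authors' deposited table the median log2 fold over control was 2.95 for Doxo, 2.52 for diMe-Doxo and 2.62 for Acla. No control peak had been called at 82.6% ± 0.732 of Doxo regions, 88.8% ± 0.613 of diMe-Doxo regions and 91.3% ± 0.571 of Acla regions (jackknife SE over chromosomes).

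Control peaks had been called at a larger share of Doxo regions than of diMe-Doxo or Acla regions. A peak in both control libraries was present at 7.44% of Doxo regions, 3.54% of diMe-Doxo regions and 2.45% of Acla regions. Doxo exceeded diMe-Doxo by 3.89 ± 0.173 percentage points and Acla by 4.98 ± 0.226 (jackknife SE). The share of regions with 1 read in each control library was 24.97% for Doxo, 32.5% for diMe-Doxo and 34.4% for Acla. These orders follow the scaling and the treated reads of the lists, whose part was not tested. A control read counted as 1.44 and 1.39 in the Doxo list, 2.41 and 2.03 with diMe-Doxo and 2.85 and 2.44 with Acla. Median reads per listed region in the treated libraries were 38 and 41, 61 and 51, and 92 and 73. The edgeR quasi-likelihood test on recovered reads called 62521, 51765 and 61146 of the listed regions higher than the control for Doxo, diMe-Doxo and Acla, at an adjusted p of at most 0.05. These regions had been selected as gained from the same libraries, so the counts are no independent check. The SD of log2 signal between treated libraries was 0.41 for Doxo, 0.28 for diMe-Doxo and 0.29 for Acla, and between the control libraries it was 1.41, 1.19 and 1.15 at the regions of these lists.

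The regions with the lowest FDR in each list were gained with all 3 drugs. The leading Doxo region, on chromosome 5 at 138726893-138729275 (GRCh37), had 532 and 591 normalized reads with Doxo against 1.44 and 1.39 in the controls, an authors' log2 fold of 8.63 (FDR 1.58e-13). Its authors' log2 fold was 5.94 with diMe-Doxo and 5.43 with Acla. Each control library held 1 read there, so the Doxo ratio of 397 had a counting interval of 110 to 3283. The region on chromosome 5 at 170736204-170738871 led the diMe-Doxo list, with an authors' log2 fold of 5.76 (FDR 5.84e-11), beside 7.58 with Doxo and 4.73 with Acla. The leading Acla region, on chromosome X at 27847980-27850484, had an authors' log2 fold of 6.28 with Acla (FDR 1.18e-09), 5.64 with diMe-Doxo and 5.53 with Doxo. Normalization differed between the lists, so folds of different drugs stand side by side without a test.

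Other regions among the 3 lowest FDRs were on chromosome 4 at 141208753-141211247 for Doxo (authors' log2 fold 7.98), on chromosome X at 125298514-125301162 and chromosome 8 at 114644649-114646469 for diMe-Doxo (5.89 and 5.84), and on chromosome 10 at 82841853-82844087 and 55769309-55771316 for Acla (6.18 and 6.16). The widest region shared by all 3 lists, 5231 bp on chromosome 4 at 100570438-100575669, was already a peak in both controls and had authors' log2 folds of 3.30, 2.65 and 1.78 with Doxo, diMe-Doxo and Acla. The widest Doxo region, 5362 bp on chromosome 22 at 19509368-19514730, was listed for Doxo only, with 246 and 288 control reads and an authors' log2 fold of 1.63. The regions on chromosome 8 at 56362283-56367167 and on chromosome 11 at 126303749-126308089 were listed for Doxo (2.91 and 3.26) and diMe-Doxo (1.76 and 1.81) but not for Acla. Wide Acla regions lay on chromosome 1 at 17083958-17088231 (2.30, and 3.51 with Doxo) and on chromosome 2 at 129024718-129028948 (2.62, with 5.02 for Doxo and 3.12 for diMe-Doxo).

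The regions listed for diMe-Doxo were largely those listed for Acla, while many regions were listed for Doxo alone. Regions of 1 drug alone were not listed for the other drugs, whose signal there is not given. A smaller gain with those drugs is possible, and no difference between drugs was tested there. Of 100205 regions in any list, 28735 (28.7%) were gained with all 3 drugs and 29528 (29.5%) with Doxo alone. Regions of Acla alone numbered 13841 and of diMe-Doxo alone 4977. A further 14667 were shared by diMe-Doxo and Acla only, against 4405 by Doxo and diMe-Doxo only and 4052 by Doxo and Acla only. The Jaccard index was 0.614 ± 0.00589 for diMe-Doxo with Acla, 0.384 ± 0.00849 for Doxo with diMe-Doxo and 0.344 ± 0.00465 for Doxo with Acla (jackknife SE). The first exceeded the second by 0.230 (95% interval 0.213 to 0.248).

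**Figure D1:**
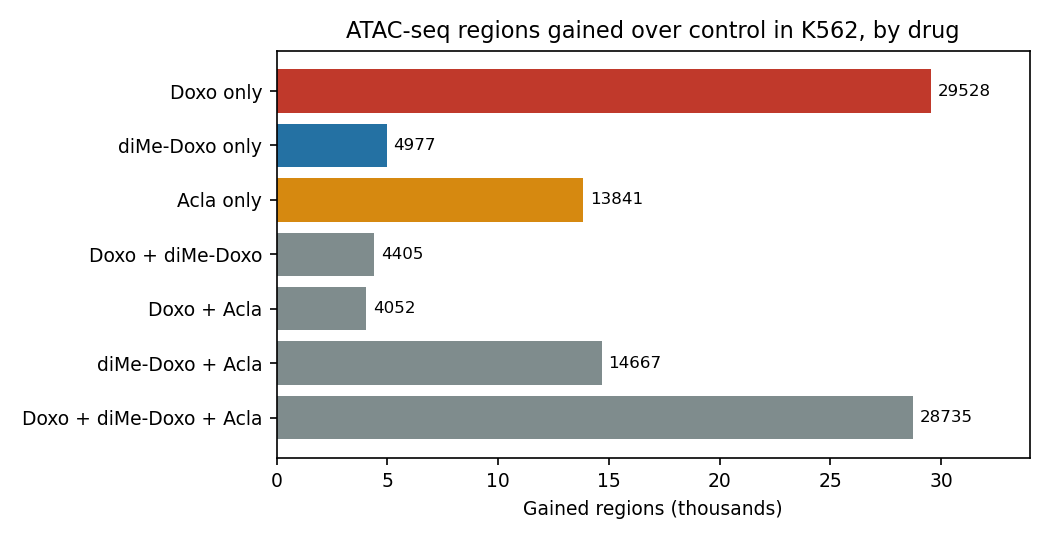
Number of gained regions (horizontal axis, in units of 1000) by the drugs for which each was listed, from all 100205 regions. Doxo alone (29528) and all 3 drugs together (28735) make the longest bars, and diMe-Doxo alone has 4977.

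Given the bound on tested regions, each pair of lists shared more regions than independent lists would. Of Doxo regions, 49.7% were also diMe-Doxo regions, against a mean of 3.35% when diMe-Doxo regions were shifted along their chromosomes and a highest value of 3.78% in 100 shifts. For Doxo with Acla the values were 49.1%, 3.84% and 4.19%, and for diMe-Doxo with Acla 82.2%, 4.10% and 4.61%. All 3 lists use the same coordinates, which shifted regions leave, so the shifts give too low a comparison. Independent lists drawn from the tested regions would share at most 16738, 19437 and 15377 regions, beside 33140, 32787 and 43402 observed. Unchanged drug libraries simulated against the shared controls passed a log2 fold of 1.5 in both comparisons at 148, 117 and 183 regions. The simulation used listed regions only, so these counts rest on fewer regions than the limits for independent lists. Part of the excess may come from the shared controls, which were not split, since a split of 2 libraries leaves 1 for each drug.

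Within each list, regions gained with all 3 drugs had higher folds than regions gained with a single drug. The split and the folds rest on the same 2 control libraries, so part of this difference is set by the selection, and no value for unchanged libraries was computed for it. Mean control reads were 2.64 and 2.28 at regions of all 3 drugs, 4.88 and 5.55 at regions of Doxo alone, 2.38 and 2.27 at regions of diMe-Doxo alone and 2.28 and 1.86 at regions of Acla alone. Median authors' log2 folds were 3.13 against 2.83 in the Doxo list, 2.82 against 2.14 in the diMe-Doxo list and 2.95 against 2.30 in the Acla list. The differences were 0.30 ± 0.02, 0.68 ± 0.03 and 0.65 ± 0.03 (jackknife SE). Of the regions shared by all 3 drugs, 14.9%, 17.6% and 19.4% were among the 10% with the highest authors' log2 fold in the Doxo, diMe-Doxo and Acla lists. Of single-drug regions, 5.00%, 0.0201% and 0.144% were. Regions of Doxo alone had a median width of 600 bp and regions of all 3 drugs 1019 bp. A peak in both controls was present at 11.9% of Doxo-only regions, 4.50% of diMe-Doxo-only regions and 1.16% of Acla-only regions. Among regions of a single drug chosen after their values were seen, the lowest FDR belonged to chromosome 7 at 64894517-64896029 for Doxo (authors' log2 fold 7.48), chromosome 10 at 61274806-61275749 for diMe-Doxo (3.81) and chromosome 5 at 13835977-13837267 for Acla (4.49).

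Doxo and diMe-Doxo, which differ by dimethylation of the amine and were given at the same dose and time, differed in how much they shared with Acla. Of diMe-Doxo regions 82.2% were also Acla regions, and of Doxo regions 49.1%, a difference of 33.1 ± 1.38 percentage points (95% interval 30.4 to 35.8). Doxo had 1.26 times as many regions as diMe-Doxo (95% interval 1.23 to 1.30, from draws of 1 Mb windows). The draws treat windows as independent, though the ratio ran from 0.969 on chromosome 4 to 3.65 on chromosome 19, so this interval may be too narrow. At an FDR of at most 0.01 and a log2 fold of at least 2 the ratio was 1.62. Of diMe-Doxo regions 62.8% ± 1.07 were also gained with Doxo, and of Doxo regions 49.7% ± 1.83 were also gained with diMe-Doxo.

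At regions in both lists, read counts were more often higher with Doxo than with diMe-Doxo. The edgeR quasi-likelihood test called 9583 of 33140 shared regions higher with Doxo and 900 lower (adjusted p at most 0.05), and 7831 higher and 3508 lower when TMM set the scale. Both scalings called 7831 regions higher and 899 lower. The median log2 difference was 0.28 with the authors' factors and -0.05 with TMM. The 900 lower calls became 158 without diMe-Doxo replicate 1 and 514 without diMe-Doxo replicate 2. The lowest adjusted p-values, at regions chosen after their values were seen, belonged to chromosome 12 at 29943974-29947090, with 539 and 635 reads with Doxo and 78 and 60 with diMe-Doxo (log2 fold 4.37, edgeR adjusted p 2.87e-70), and to chromosome 4 at 141208753-141211247, with 698 and 810 against 115 and 74 reads (log2 fold 4.28, edgeR adjusted p 2.87e-70). With TMM both had an edgeR adjusted p of 5.65e-13.

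With Acla at 20 µM beside Doxo at 10 µM, the doses differed. Of 32787 shared regions, edgeR called 8734 higher with Doxo and 3700 lower, or 7710 and 6144 with TMM. The lower calls fell to 943 without Acla replicate 1 and to 1774 without Doxo replicate 1. The region with the lowest adjusted p, chosen after its values were seen, was on chromosome 4 at 48491667-48494203, with 706 and 828 reads with Doxo and 99 and 116 with Acla (log2 fold 4.63, edgeR adjusted p 1.94e-150). With TMM its log2 fold was 4.41 and its edgeR adjusted p 1.63e-14, so the size of p depended on the fit far more than the fold did. The edgeR fit shares variance between regions, so such a p does not measure the spread between libraries at this region alone.

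Between diMe-Doxo and Acla, also at different doses, the calls at shared regions were the least stable. Of 43402, edgeR called 367 higher with diMe-Doxo and 2421 lower, or 2884 and 3612 with TMM. The counts also changed with the libraries kept. A fit with 1 library in a group has less power, so these changes do not show that the calls rested on a single library. The median log2 difference was -0.15 with all libraries. It was -0.01 and -0.28 without Acla replicate 1 or 2, and -0.29 and -0.05 without diMe-Doxo replicate 1 or 2. The region with the lowest adjusted p, on chromosome 6 at 166720213-166722353 and chosen after its values were seen, had 596 and 422 reads with diMe-Doxo and 240 and 264 with Acla (log2 fold 1.53, edgeR adjusted p 9.58e-08, or 1.34e-09 with TMM).

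The authors' log2 folds of diMe-Doxo and Acla followed each other more closely than either followed Doxo. Across shared regions, which are not independent replicates, Pearson's r was 0.762 for diMe-Doxo with Acla, 0.394 for Doxo with diMe-Doxo and 0.238 for Doxo with Acla, and Spearman's rho was 0.700, 0.372 and 0.230. Unchanged libraries simulated against the shared controls gave r of 0.680, 0.590 and 0.611. Only 183, 148 and 117 simulated regions passed a log2 fold of 1.5 in both comparisons, whereas every listed region had. Simulated correlations and covariances are therefore no like baseline for the listed ones, and no conclusion is drawn from the gaps. The covariance was 0.363 beside 0.344 simulated for diMe-Doxo with Acla, 0.263 beside 0.334 for Doxo with diMe-Doxo and 0.180 beside 0.338 for Doxo with Acla.

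Doxo regions were spread differently over the chromosomes. Chromosome 19 held 2501 Doxo, 685 diMe-Doxo and 1070 Acla regions, a Doxo to diMe-Doxo ratio of 3.65 (95% interval 3.14 to 4.22) beside 1.26 over the genome. Its size depended on which regions were counted, with 7.07 beside 1.62 over the genome at an FDR of at most 0.01 and a log2 fold of at least 2, and 2.13 at regions with no control peak and 1 read in each control library, where the ratio over the genome was 0.966. The ratio was 3.37 on chromosome 22 (2.66 to 4.33), 2.42 on chromosome 17 (2.05 to 2.87) and 2.18 on chromosome 16 (1.81 to 2.60). Chromosome 4 had 3424 Doxo and 3532 diMe-Doxo regions, a ratio of 0.969 (0.876 to 1.07). Chromosomes 16, 17, 19 and 22, chosen after their values were seen because their ratios were the highest among chromosomes 1 to 22 and X, together held 12.3% of Doxo regions, 5.75% of diMe-Doxo regions and 6.53% of Acla regions. The Acla to diMe-Doxo ratio lay between 1.08 on chromosome 7 and 1.56 on chromosome 19. K562 cells are aneuploid, so drugs were compared within a chromosome.

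**Figure D2:**
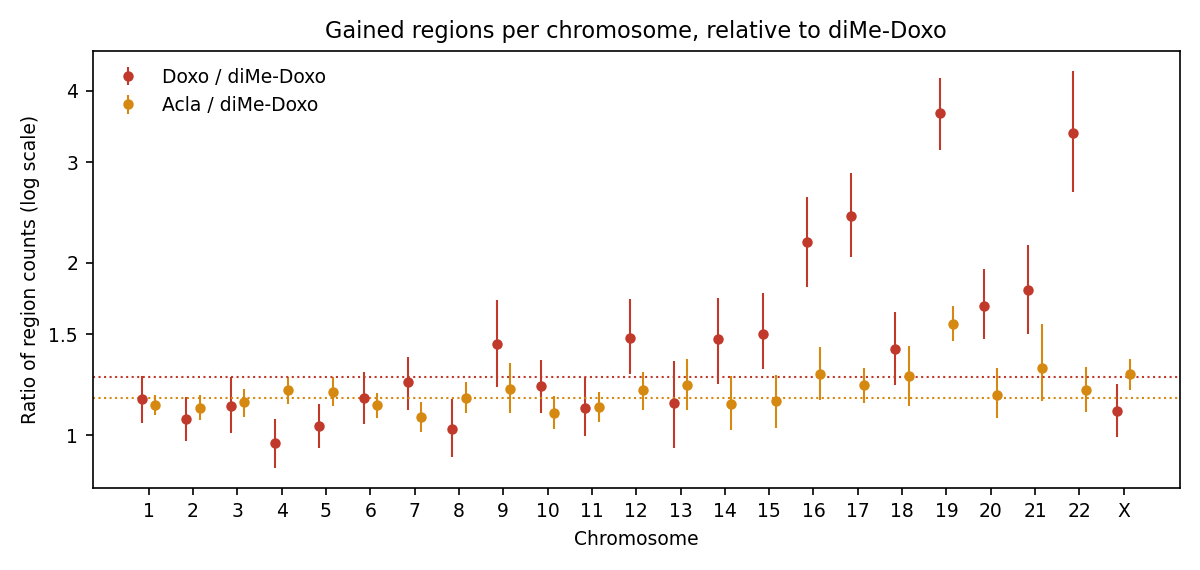
Ratio of the number of gained regions with Doxo (red) and with Acla (orange) to that with diMe-Doxo (vertical axis, log scale) for chromosomes 1 to 22 and X, with 95% intervals from resampled 1 Mb windows and dotted lines at the ratios over the genome. The Doxo ratio reaches 3.65 on chromosome 19 and 3.37 on chromosome 22, and is 0.969 on chromosome 4.

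The difference on chromosome 19 was also present at regions gained with both drugs. Of 616 such regions on chromosome 19, edgeR called 374 higher with Doxo than with diMe-Doxo and 0 lower, with 397 higher and 0 lower at an unadjusted p under 0.05 and 3 lower with TMM. The median log2 difference was 1.23 on chromosome 19 and 0.17 on chromosome 4, or 0.90 and -0.16 with TMM. Of Doxo regions on chromosomes 19 and 22, 62.1% and 67.8% were gained with Doxo alone, against 33.8% on chromosome 4 and 44.3% over the genome.

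Among 1133 windows of 1 Mb with at least 60 entries over the 3 lists, 544 held more Doxo than diMe-Doxo regions and 567 held fewer. Doxo regions were most numerous on chromosome 7 at 1-2 Mb and 2-3 Mb (155 in each, with 90 and 73 for diMe-Doxo) and on chromosome 16 at 89-90 Mb (146, with 27 for diMe-Doxo). The diMe-Doxo regions were most numerous on chromosome 8 at 143-144 Mb (162, with 119 for Doxo), chromosome 1 at 4-5 Mb (151, with 92 for Doxo) and chromosome 7 at 157-158 Mb (136 with either drug). Acla regions were most numerous on chromosome 1 at 4-5 Mb (150) and 177-178 Mb (135, with 52 for Doxo) and chromosome 11 at 132-133 Mb (134, with 46 for Doxo). In windows chosen after their values were seen, the 1 Mb from 122 Mb of chromosome 12 held 66 Doxo, 1 diMe-Doxo and 2 Acla regions, and chromosome 8 at 109-110 Mb held 7, 36 and 42. Across 2848 windows, which are not independent replicates, Spearman's rho of region counts was 0.923 ± 0.00377 for diMe-Doxo with Acla, 0.627 ± 0.0208 for Doxo with diMe-Doxo and 0.451 ± 0.0210 for Doxo with Acla (jackknife SE).

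**Figure D3:**
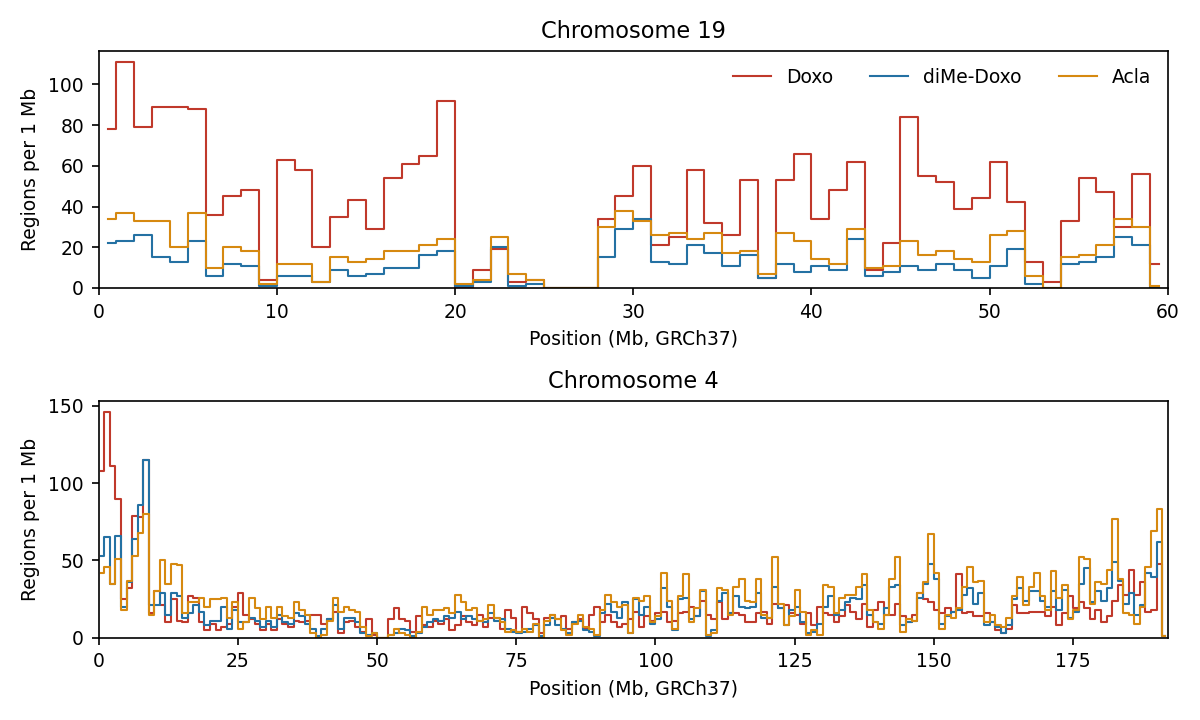
Gained regions per 1 Mb window (vertical axis) along chromosomes 19 and 4 (horizontal axis, Mb of GRCh37) for Doxo (red), diMe-Doxo (blue) and Acla (orange). On chromosome 19 the highest window holds 111 Doxo regions, 34 diMe-Doxo regions or 38 Acla regions, and on chromosome 4 it holds 146, 115 or 83.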

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

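The limits of FDR 0.01 with log2 fold 2, the edgeR tests, the settings without a library, and for chromosome ratios the equal-length and no-control-peak settings were chosen after seeing the data. Taking the better-ranked 50% of each list left 33360, 26392 and 30647 regions for Doxo, diMe-Doxo and Acla by construction, and the limits of FDR 0.01 with log2 fold 2 left 32564, 20111 and 26254. In the order Doxo with diMe-Doxo, Doxo with Acla, diMe-Doxo with Acla, Jaccard indices were 0.279, 0.221 and 0.544 in the better-ranked 50%, 0.411, 0.371 and 0.630 with regions within 1 kb merged, and 0.267, 0.216 and 0.519 under the stricter limits. With lists of equal length the first pair of these was 0.348 and 0.297. Leaving out each library or chromosome in turn gave 0.365 to 0.388, 0.329 to 0.346 and 0.600 to 0.616. Without a library, listed regions can drop out but none can enter, because the lists had been selected with all libraries, so these ranges, and those without single libraries given next, are partly fixed by construction. In each of these settings diMe-Doxo with Acla had the highest index. Local shifts by 100 kb to 1 Mb, which also leave the shared coordinates, met 4.97%, 5.12% and 6.32% of regions. The excess of diMe-Doxo over Doxo in regions shared with Acla was 41.5 points in the better-ranked 50%, 30.1 with equal lengths, 46.7 under the stricter limits and 32.7 to 36.1 without single libraries. The Doxo to diMe-Doxo ratio on chromosome 19 was 3.02 by covered length, 3.13 with merged regions, 7.07 under the stricter limits, 3.10 with equal lengths, 3.36 without control peaks and 3.62 to 4.03 without single libraries. On chromosome 4 it was 1.14 under the stricter limits, 0.736 with equal lengths, 0.899 without control peaks and 0.948 to 1.04 without single libraries, so its side of 1 depended on the setting. Regions that differed between diMe-Doxo and Acla numbered 6496 with TMM and 17 to 5397 without single libraries, where the lone library is assumed to vary like the others. The cause of these shifts was not tested. Requiring 50% overlap or a midpoint changed nothing, because regions matched exactly or not at all. Of the alternatives judged as counts, 33 stayed within 1.5 times the reported count and 11 did not. Of those judged as values with an error, 112 moved by at most that error and 33 by more. Many of the 112 were fixed by construction. They include the values without 1 chromosome, from which the error itself is computed, and the 50% overlap and midpoint rules. The share among the 10% with the highest authors' log2 fold kept the direction of the fold difference in all 3 lists. It is that same fold cut at a limit, so it is no separate check. Gene position, promoter list and GC-matched alternatives were not run, since no GRCh37 annotation or genome was used here. No paired fit was run, because the labels carry no replicate numbers, and the numbers used here follow the order of the values in the lists and only name the libraries. The unknown depth and control counts of 1 read limit how well folds in unopened chromatin are measured.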

Other observations

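The test on the better-ranked 50% of each list and the counts near chromosome ends were chosen only after the result was seen. Gained regions were dense near chromosome ends with all 3 drugs. Within 10 Mb of an end, taking the last listed region as the far end and leaving out the short arms of chromosomes 13, 14, 15, 21 and 22, Doxo had 47.4 regions per Mb against 18.6 elsewhere, a ratio of 2.54 ± 0.152 (jackknife SE). The ratio was 2.29 ± 0.122 for diMe-Doxo and 2.01 ± 0.0951 for Acla. These stretches held 30.3% of Doxo-only, 27.0% of diMe-Doxo-only and 17.6% of Acla-only regions, 30.9% of regions of Doxo and diMe-Doxo, 24.7% of Doxo and Acla, 23.5% of diMe-Doxo and Acla, and 28.2% of regions of all 3 drugs. The differences between these classes were not tested. Tested regions and control peaks were not counted in this way, so the density of gained regions near ends has no baseline. Stretches of 10 Mb also make up more of short chromosomes such as 19, where Doxo regions were in excess. The differences between drugs near ends are therefore not separate from those between chromosomes.

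The Doxo list stood apart from the lists of diMe-Doxo and Acla. A log2 fold limit that lists too many Doxo regions would let some pair of stricter limits bring the lists together. The highest Jaccard index of Doxo with diMe-Doxo over limits of 1.5 to 4 was 0.385, beside 0.614 for diMe-Doxo with Acla. With equal lengths it was 0.348 beside 0.610. Stricter limits only remove regions, so they cannot show whether scaling kept regions out of the diMe-Doxo and Acla lists. A treated read counted as 0.711 and 0.704 in the 2 Doxo libraries, 0.446 and 0.460 with diMe-Doxo and 0.374 and 0.384 with Acla. A control read counted as 1.44 and 1.39, 2.41 and 2.03, and 2.85 and 2.44 in these lists. Weak regions were tested first on the 1000 regions of lowest FDR, of which 90.7% of Doxo and 100% of Acla regions were in the diMe-Doxo list, a gap too small for the bound of 10 points set beforehand. In the better-ranked 50%, a test added because that one was undecided, the shares were 54.3% and 89.1%, which argues against weak regions as the whole cause, though the Doxo list did hold more weak regions, with no peak in either treated library at 12.3% of its regions against 6.10% for diMe-Doxo and 6.36% for Acla. A different chromatin response to Doxo may remain as a hypothesis. The scaling of the lists and a batch difference between libraries, of which the labels say nothing, stay open.

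The excess of Doxo regions on chromosome 19 was set against control openness and list length. Among regions with no control peak and 1 read in each control library, the Doxo to diMe-Doxo ratio on chromosome 19 was 2.13 beside 0.966 for all such regions, with an error of 0.168. With lists of equal length it was 3.10 ± 0.241. The second value argues against list length as the whole cause, and the first against control openness that these libraries can show. Differences in openness below 1 control read could not be tested. GC content, which may differ between chromosome 19 and the rest, was not tested without a genome, so a sequence bias of the libraries and a biological preference of Doxo both stay open.

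The deposited p-values and FDRs set a lower limit on regions outside the lists. If the FDR is a Benjamini-Hochberg adjustment, which makes ties, at least 8.56% of tested regions for diMe-Doxo and 11.8% for Acla, against 0.265% for Doxo, lay at or below the lowest FDR in the list. Gained regions with a log2 fold just under 1.5 are an unlikely source, because the lowest p at a log2 fold of 1.5 to 2 was at least 12949640 times the lowest p in the list. Whether these regions lost signal is open and was not tested, because regions with less signal than the control were not analysed here. A test of such regions against the same controls would decide it.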
